A study of Homo sapiens with 4 samples.

How the data were processed

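Single-cell expression and cell hashing were measured at day 6 of a cardiac differentiation of human WTC CRISPRi GCaMP induced pluripotent stem cells, per the labels. The 4 samples are 1 expression matrix and 1 hashtag matrix labelled control, and 1 of each labelled knockdown of the long noncoding RNA NKX2-6-AS1, also named the clone-based name in the labels. Per the labels, cells of each condition carried their own TotalSeq-A hashing antibody, were pooled with other samples of a larger run and were sorted for viability before capture on a 10x Chromium instrument.

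The deposited expression matrices hold raw UMI counts per gene and cell barcode, and the deposited hashtag matrices hold raw counts per tag and cell barcode. The submitters' processing notes name the build GRCh38 and the tools Cell Ranger and Seurat, without a role for either tool. Per the file headers, the control-labelled matrix came from version 3.1.0 and the knockdown-labelled matrix from Cell Ranger 6.0.1. No barcode in either expression matrix had fewer than 500 UMIs. Which tool counted the hashtags, and whether it counted reads or UMIs, is not given in the sources used here. Gene positions were taken from GENCODE 29 on GRCh38.

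Barcodes were kept with at least 500 detected genes, at least 1000 UMIs and at most 20% mitochondrial UMIs. Scrublet in scanpy 1.11.5, run on each matrix alone, called 13.7% of these doublets in the control-labelled matrix and 14.0% in the knockdown-labelled matrix, and these were left out. UMIs were summed over the remaining cells of each matrix for the 32732 gene IDs in both feature lists and scaled to counts per 1e6 UMIs (CPM) of those sums. Ratios are log2 of the knockdown-labelled over the control-labelled value with 1 CPM added to each, except for NKX2-6, AC012574.1 and the interval of any single gene, which are given without it. Sums carry an exact Poisson interval, ratios of sums an exact conditional interval and shares an exact Clopper-Pearson interval, each at 95%. Where no cell had a UMI, the text gives the share that 3 cells would make up, in place of the Clopper-Pearson bound. These intervals and limits cover counting error only. Intervals of ratios and of medians of ratios treat the matrices as independent, which the comparison of barcodes below contradicts. With 1 library there is no test, no p-value and no count of changed genes.

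The gene lists, cell type markers, cell filter, clustering settings and the rule for named genes were fixed before the data were examined. That rule takes genes with an ID in both feature lists and leaves out ribosomal protein, mitochondrial and sex-linked marker genes and clone-based names. The named genes are the 12 largest and the 12 smallest ratios among genes at 20 CPM or more in either matrix, the target and its 8p21 neighbours, up to 4 members of each fixed list with the largest absolute ratio among those at 5 CPM or more, and the 3 largest and 3 smallest ratios within each class among genes at 50 CPM or more. A list's median ratio over members at 5 CPM or more was placed among the medians of 10000 random lists matched on mean expression. There were 31 lists, 15 of cell type markers and 16 of pathways or positions.

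Both matrices were clustered together on log-normalised values with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, using igraph 0.11.9 and leidenalg 0.10.2. A cluster took the name of the marker list with most members at 20 CPM or more and at least 1 log2 unit above the mean of the other clusters, given at least 3 such members. It stayed unnamed where another list held more of its 10 leading genes, or where its cells were shallow and held none of the list's genes among the leading ones. The markers were fixed beforehand; the settings of this naming rule were chosen after the clusters had been seen. Cell cycle phases were called by scanpy from the fixed S phase and G2 and M phase lists after thinning each cell to 2000 UMIs, which left out 273 and 288 cells. A hashtag was called at the lowest point of its count histogram between the background and the upper mode, a rule set after the histograms had been seen. The tags are named C0251 to C0255 in the control-labelled hashtag library and A0251 to A0258 in the knockdown-labelled one. The labels name TotalSeq-A antibodies, and whether the C-named tags are of that type was not checked. No name ties a hashtag to a condition, so all cells of a matrix were used as 1 pooled library.

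The matrices were compared barcode by barcode over shared genes. For 2000 sampled barcodes the profile in one matrix was correlated with the profile of the same barcode and of another barcode in the other matrix. Alternatives covered the cell filter, doublets, hashtag calls, the weight of cells, the scaling, the pseudocount, the minimum CPM, the clustering and the thinning. The pipeline was tested on simulated data. Genes simulated 2-fold higher came back at a median of 1.90-fold, and none of 10089 unchanged genes passed 0.5 log2. A raised list reached percentile 100, 1.5% and 1% of unchanged lists fell in the lower and upper tails, and the clustering recovered the 6 simulated populations. Hashtag calls were right for 99.3% of simulated barcodes, in which every tag had the same depth and background. In the data the thresholds ran from 8 (C0254) to 112 counts (C0251), so that share may not carry over. The clustering simulation held a single quantification, so it did not test a split of clusters by matrix. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. The levels of sex-linked genes were left out.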

Results

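Human induced pluripotent stem cells of the WTC CRISPRi GCaMP line were taken at day 6 of a cardiac differentiation. The line carries an inducible CRISPR interference system, in which a guide RNA directs a repressor to a chosen gene. The culture received 3 μM of the GSK3 inhibitor CHIR99021 for 3 days and fresh medium on day 5, without the Wnt inhibitor Xav. Per the labels, the cells were pooled with other samples of a larger run before capture, so a matrix may hold cells of other samples. Of the 4 samples, 1 expression matrix and 1 hashtag matrix are labelled control, and 1 of each is labelled doxycycline-induced knockdown of NKX2-6-AS1, so no group had replicates. The control-labelled expression matrix held 431125194 UMIs over 25691 barcodes, with a median of 16026 UMIs per barcode. The knockdown-labelled expression matrix held 450643345 UMIs over 25747 barcodes, with a median of 16680. Both barcode numbers exceed the 20000 cells that the labels say were loaded. The control-labelled hashtag matrix held 4701916 counts of 5 tags over 25687 barcodes, with a median of 32 per barcode, and the knockdown-labelled one 11695187 counts of 8 tags over 29381 barcodes, with a median of 209. After the cell filter and doublet removal, 17282 and 17290 cells remained, with medians of 18403.5 and 19208 UMIs.

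The design asks what the knockdown of NKX2-6-AS1 does to cardiac differentiation. NKX2-6 encodes an NK-family homeobox protein of the pharyngeal region and early heart. The 2 expression matrices shared 25655 barcodes, 99.9% of the control-labelled and 99.6% of the knockdown-labelled set. Over genes in both feature lists, UMIs per shared barcode correlated at r = 0.99999 across barcodes, and 93.0% of the nonzero entries were identical. The profile of a barcode in one matrix correlated with that of the same barcode in the other at a median of 0.986, with a lowest value of 0.973, over 2000 sampled barcodes. Different barcodes correlated at a median of 0.726 and reached at most 0.893. Gene totals lay within 1 Poisson SD of each other for 38.1% of 17332 genes when scaled by all UMIs, and for 84.3% when scaled by the median gene ratio, a scaling added after the first value had been seen. For independent libraries 68.3% is the value from theory. The matrices therefore hold counts of the same cells, and no value given here sets knockdown cells against control cells. Intervals of ratios treat the matrices as independent, which they are not, so they do not measure the error of a ratio between them.

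NKX2-6 (ENSG00000180053, minus strand of chromosome 8, 23702451 to 23706598 on GRCh38) had 34 UMIs in the filtered cells of each matrix. That is 0.106 CPM (95% interval 0.0736 to 0.149) in the control-labelled and 0.103 CPM (0.0711 to 0.143) in the knockdown-labelled matrix, a log2 ratio without the added CPM of -0.05 (-0.78 to 0.68). A pair of long noncoding RNA genes lies beside it. AC012574.1 (ENSG00000253471) starts on the plus strand at 23707141, next to the start of NKX2-6, and runs to 23789487. It had 7 and 8 UMIs, or 0.0219 CPM (0.0088 to 0.0451) and 0.0241 CPM (0.0104 to 0.0476), a log2 ratio without the added CPM of 0.14 (-1.52 to 1.84). AC012574.2 (ENSG00000254002), on the minus strand from 23726331 to 23743042, had 16 and 21 UMIs. The sources used here do not pair the target's names in the labels with either identifier, so neither value is given as that of the target. STC1, which encodes the secreted hormone stanniocalcin, had 2541 UMIs in both matrices. Across the 12 members of the 8p21 neighbour list at 5 CPM or more the median log2 ratio was -0.0460, at percentile 2.04 of matched random lists, and the members with the largest absolute ratios were NEFL (-0.05), NEFM (-0.05), CDCA2 (-0.05) and DOCK5 (-0.05).

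**Figure D1:**
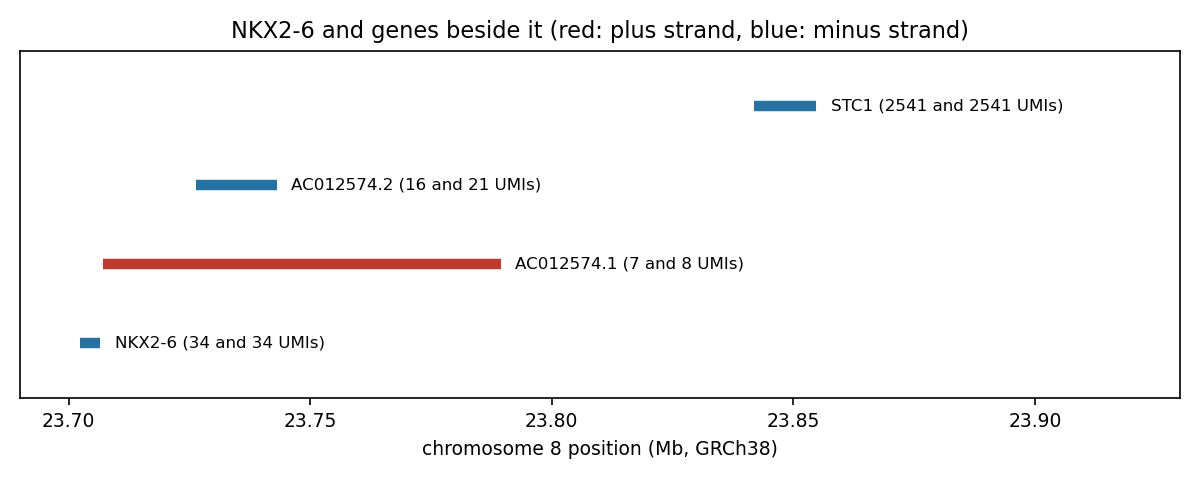
NKX2-6 and genes beside it on chromosome 8, drawn to scale against their GRCh38 position in Mb, red on the plus and blue on the minus strand, with the UMIs of each in the control-labelled and the knockdown-labelled matrix. NKX2-6 has 34 UMIs in each matrix and AC012574.1 has 7 and 8.

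In the control-labelled matrix clustered alone, 23 of its 34 UMIs were in the 938 cardiomyocyte-like cells, at 1.76 CPM (1.12 to 2.65). Unnamed clusters held 8 UMIs, definitive endoderm-like cells 2 and mesenchymal and smooth muscle-like cells 1. An NKX2-6 UMI was found in 2.45% of cardiomyocyte-like cells, whose median depth was 13413.5 UMIs. In pluripotent-like cells, with a median of 24845 UMIs, 0 of 4525 cells had one, which allows up to 0.0663%. The second heart field and pharyngeal-like class, for which NKX2-6 is a listed marker, had 0 UMIs in 1483 cells, which allows up to 0.202% of cells with one at a median of 9358 UMIs. AC012574.1 had 5 of its 7 UMIs in cardiomyocyte-like cells, at 0.384 CPM (0.124 to 0.895). That class depends on the clustering. A cluster with 573 of its cells had 8 of 13 cardiomyocyte markers and 7 of 10 cardiac progenitor markers. The cluster with the remaining 365 cells had 11 and 7. With both matrices clustered together, the cardiomyocyte-like class held only 122 control-labelled cells. Class and hashtag population are confounded here: 780 of the 938 cardiomyocyte-like cells carried hashtag C0255, which held 25 of the 34 NKX2-6 UMIs, and C0252, C0253 and C0254 held 0.

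Marker and pathway lists had nearly the same levels in both matrices, with each median slightly below 0 under the reported filter and scaling. Under median-of-ratios scaling 22 of 31 lay above 0, and under the stricter cell filter the paraxial mesoderm (0.0234) and posterior HOX and CDX (0.0347) lists did. The pluripotent list, which includes the stem cell factor POU5F1 (log2 ratio -0.05), had a median log2 ratio of -0.0474 over 8 members at 5 CPM or more, at percentile 26.4 of matched random lists. The cardiac progenitor list had -0.0428 over 7 members, at percentile 30.7. The cardiomyocyte list of sarcomere genes had -0.0336 over 9 members, at percentile 99.4, and the definitive endoderm list -0.0379 over 10, at percentile 98.2. The endothelial list had only 2 members at that level, with a median of -0.0501, at percentile 7.54. All 31 medians lay between -0.06 and 0, from -0.0503 for the primitive streak list to -0.0166 for the amnion and extraembryonic list. The primitive streak (percentile 0.245), second heart field and pharyngeal (1.46), anterior HOX (1.14) and 8p21 neighbour lists lay lowest among their random lists, and the amnion and extraembryonic (97.7), cardiomyocyte and definitive endoderm lists highest. The simulation of such percentiles drew independent matrices, so it does not calibrate them for counts of the same cells. The stricter cell filter kept 12748 control-labelled and 13510 knockdown-labelled cells, and no percentiles were computed under it. There the cardiomyocyte (-0.0618), definitive endoderm (-0.0730) and amnion and extraembryonic (-0.0503) medians were lower and the anterior HOX median (-0.0003) higher. The primitive streak (-0.0595), second heart field and pharyngeal (-0.0726) and 8p21 neighbour (-0.0512) medians were lower as well. Median-of-ratios scaling, whose size factor against totals was -0.0466 on the log2 scale and which therefore raised the medians, gave values from -0.005 to 0.0279. The mean lay above 0 for the cardiac mesoderm, paraxial mesoderm, neural, BMP and Notch lists, each of which has 1 member at 0.50 or more.

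Among the 222 list members at 5 CPM or more, 211 lay within 0.1 log2 of 0 and 6 reached 0.5. MSGN1, a transcription factor gene of the presomitic mesoderm, had a log2 ratio of 5.67, and TUBB3, which encodes a neuronal tubulin, had 6.09. The Notch feedback gene NRARP had 1.19, SMAD7, an inhibitor of BMP and TGF-beta signalling, 0.79 and HAS2, a hyaluronan synthase gene of cushion formation, 0.50. ASNS, which encodes asparagine synthetase, had -3.49. Other members named by the rule stayed closer to 0, among them RRM2 (0.21) of the S phase list, SPRY2 (0.15) of the FGF response list and COL4A2 (0.13) of the TGF-beta and extracellular matrix list.

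EEF1G (ENSG00000254772, chromosome 11, 62559601 to 62574086), which encodes a subunit of translation elongation factor 1, had 701 UMIs in the control-labelled and 616242 in the knockdown-labelled matrix, a log2 ratio of 9.19. Without the added CPM, the interval of its log2 ratio ran from 9.62 to 9.84. TOMM6 (ENSG00000214736, chromosome 6, 41787662 to 41789898), a subunit gene of the mitochondrial import pore, had 0 and 94321 UMIs, so it was at least 30360-fold higher in the knockdown-labelled matrix against a floor of 3 counts over the matrix. MSGN1 (ENSG00000151379, chromosome 2, 17816496 to 17817101) had 154 and 24649 UMIs. The other named genes with higher values were NME2, ATP6V0C, MRPS24, TUBB3, RNASEK, TRAPPC5, DBNDD2, GABARAP and GNG10, whose log2 ratios ran from 7.38 for NME2 to 5.62 for GNG10. Lower values in the knockdown-labelled matrix were led by the phosphatase gene PTP4A1 (ENSG00000112245, chromosome 6, 63521746 to 63583377), with 9876 and 5 UMIs and a log2 ratio of -4.97. Without the added CPM, the interval of that ratio ran from -12.62 to -9.78. The genes CHTF8 (-4.37), NLRP1 (-4.02), FKBP2 (-3.77), CHD1L (-3.59) and ASNS followed. Ratios for SNRPD3, RAMMET, UBR4, C16orf72, the glycolytic gene PGAM1 and LMO4 ran from -1.69 to -0.82. Of the 12 named genes with higher values, 11 had exons that overlapped, on the same strand, those of a gene model listed only in the control-labelled feature list, as NME2 does with NME1-NME2 and DBNDD2 with SYS1-DBNDD2. Of the 12 with lower values, 4 overlapped one listed only in the knockdown-labelled feature list, where only 1884 of 3870 such models could be placed. LMO4, less than 2-fold lower, was not checked. Among genes within 1.1-fold the shares were 3.46% and 0.777%. Among all 10472 genes at 5 CPM or more, 93.5% lay within 0.1 log2 of 0.

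**Figure D2:**
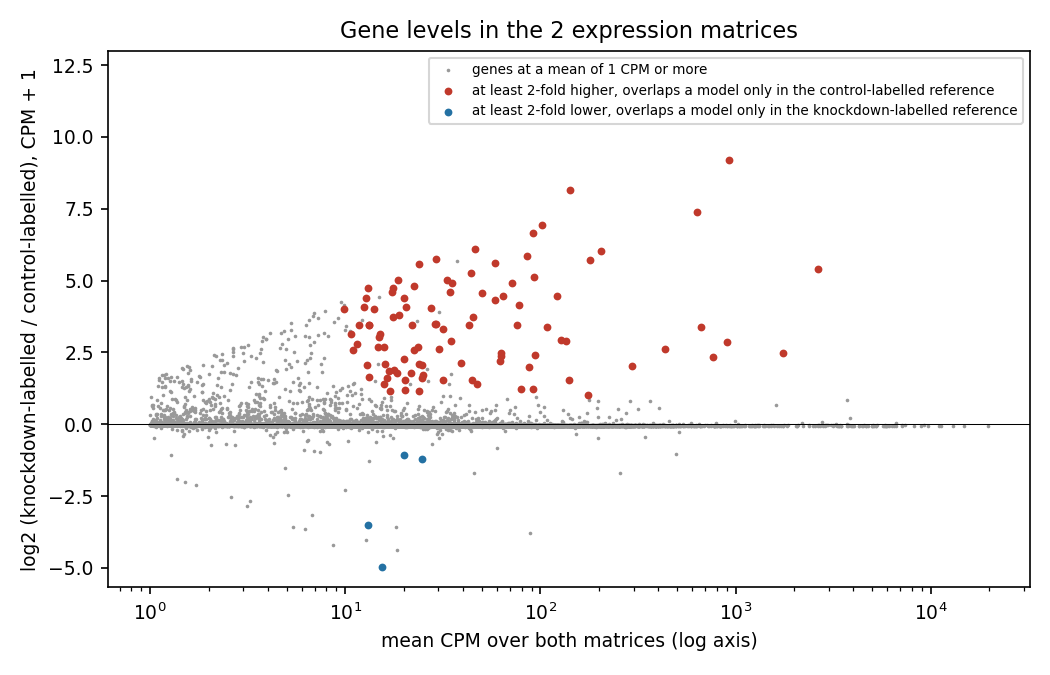
Log2 ratio of the knockdown-labelled over the control-labelled CPM, with 1 CPM added, against the mean CPM of both matrices on a log axis, for genes at a mean of 1 CPM or more. Grey points are all these genes. Red points are those at least 2-fold higher that overlap a model listed only in the control-labelled features, 99 of 115. Blue points are those at least 2-fold lower that overlap one listed only in the knockdown-labelled features, 4 of 11. Overlaps could be seen only for models with exons in GENCODE 29, 724 of 806 control-only and 1884 of 3870 knockdown-only models.

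Pluripotent-like cells were the largest named class, with 26.6% of the control-labelled cells (25.9 to 27.3) and 22.9% of the knockdown-labelled cells (22.3 to 23.6). Paraxial mesoderm-like cells made up 10.0% (9.57 to 10.5) and 11.6% (11.1 to 12.1). Second heart field and pharyngeal-like cells made up 8.45% (8.04 to 8.87) and 8.49% (8.08 to 8.92), and definitive endoderm-like cells 5.29% (4.96 to 5.64) and 7.37% (6.98 to 7.77). Mesenchymal and smooth muscle-like cells were 2.08% and 2.06%, cardiomyocyte-like cells 0.706% and 0.711% and endothelial-like cells 0.446% and 0.451%. The clusters named primitive streak-like held 0.006% (1 cell) and 19.0% (18.4 to 19.6), but none of that list's markers was among their 10 leading genes, so the name is uncertain. The same holds for 1 of the pluripotent-like clusters, with 1154 of the 4598 control-labelled cells of that class. The unnamed clusters held 46.4% and 27.4%. Of the 28 clusters, 15 had over 90% of their cells from 1 matrix. Among 17104 barcodes that passed in both matrices, 38.9% fell in the same cluster both times and 77.0% in the same class. The shares therefore describe how the same viability-sorted cells were grouped in each matrix and are not compared between conditions. As the cells were pooled with other samples, the shares may mix samples and cannot be read as the make-up of the day 6 culture. With the control-labelled matrix clustered alone, 4176 of its 4525 pluripotent-like cells carried no tag. Among the unnamed clusters, 1 of 864 and 866 cells had 8 cardiomyocyte markers and 1 of 599 and 602 cells had 6 cardiac progenitor markers. Clustered alone, the cardiomyocyte-like class took up 5.43% and 5.53% of cells and the primitive streak-like class 11.4% and 15.8%.

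**Figure D3:**
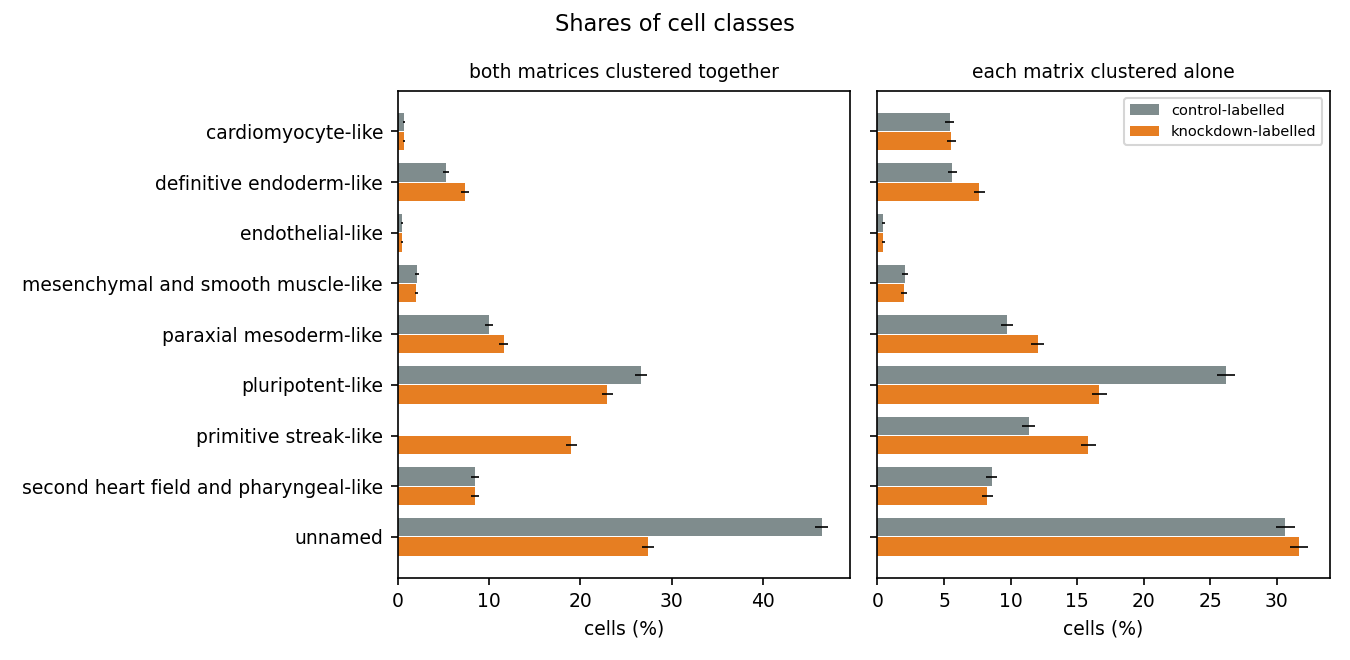
Percent of cells in each class, for the control-labelled (grey) and knockdown-labelled (orange) matrix, with both matrices clustered together on the left and each clustered alone on the right; error bars are exact 95% Clopper-Pearson intervals. The clusters named primitive streak-like on the left, a name that is uncertain, hold 0.006% and 19.0%, although the matrices hold the same cells.

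EEF1G and TOMM6 were among the 3 largest ratios in all 6 named classes compared, cardiomyocyte-like, definitive endoderm-like, mesenchymal and smooth muscle-like, paraxial mesoderm-like, pluripotent-like and second heart field and pharyngeal-like, with EEF1G between 9.08 and 9.50. FKBP2, which encodes a prolyl isomerase of the endoplasmic reticulum, was among the 3 smallest in all 6, between -4.60 and -3.59. NME2 or ATP6V0C completed the largest ratios, and NLRP1, CHD1L, RAMMET or SNRPD3 the smallest. Median log2 ratios within these classes ran from -0.046 in definitive endoderm-like cells to -0.035 in cardiomyocyte-like cells. Of 2509 genes in definitive endoderm-like cells, 48.4% lay within 0.1 log2 of 0 and 91.2% within 0.5. In the other 5 classes 85.03% (pluripotent-like) to 94.6% (mesenchymal and smooth muscle-like) lay within 0.1. The definitive endoderm-like class held 915 control-labelled and 1274 knockdown-labelled cells, including a cluster with 0 and 357. Under the stricter cell filter it held 848 and 855 cells, and 94.5% of 2422 genes lay within 0.1. The pluripotent-like class had 81.2% within 0.1 under that filter. In the pluripotent-like, paraxial mesoderm-like and definitive endoderm-like classes, different clusters held the cells of the 2 matrices.

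S phase was called for 20.5% (19.9 to 21.2) of control-labelled and 22.6% (22.0 to 23.3) of knockdown-labelled cells, and G2 or M phase for 17.1% (16.5 to 17.6) and 19.6% (19.0 to 20.2). The replication genes of the S phase list had a median log2 ratio of -0.0420 and the mitotic genes of the G2 and M phase list -0.0463. Without thinning the S phase shares were 24.95% and 26.4% and the G2 or M phase shares 19.0% and 18.7%, so the order of the latter turned. At 1000 UMIs per cell the order of both turned, with S phase at 15.1% and 13.4% and G2 or M phase at 17.9% and 16.5%. The matrices hold the same cells and the order turned with the thinning, so these differences are not differences between conditions. The share of free RNA in the calls of either matrix was not tested.

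In the control-labelled matrix clustered alone, levels by cell class are given for single genes of the fixed pathway lists. These genes lie outside the markers that named the classes. They were chosen after their values had been seen, so they do not describe their lists. Class and hashtag population are confounded in these levels too. C0251 marked 791 of 970 definitive endoderm-like and 67 of 77 endothelial-like cells. C0255 marked 780 of 938 cardiomyocyte-like cells, a class that depends on the clustering. Of 1678 paraxial mesoderm-like cells, 1560 carried no tag. The BMP target ID1 reached 1331 CPM (1259 to 1406) in endothelial-like cells and 979.9 CPM (964 to 996) in definitive endoderm-like cells, while BAMBI, a BMP and TGF-beta pseudoreceptor gene, reached 542 CPM (529 to 555) in cardiomyocyte-like cells. The Wnt inhibitor DKK1 had 1671 CPM (1658 to 1684) in paraxial mesoderm-like and 1177 CPM (1167 to 1187) in primitive streak-like cells, and NKD1, a Wnt feedback gene, had 83.7 CPM (80.8 to 86.6) in paraxial mesoderm-like cells. HOXB4, a patterning gene of the body axis, had 53.2 CPM (49.3 to 57.3) in cardiomyocyte-like cells. The Notch ligand gene JAG1 had 98.0 CPM (92.7 to 103) and the FGF response gene DUSP6 284 CPM (275 to 294) in the same class. The Hedgehog receptor gene PTCH1 had 139 CPM (133 to 145) and CRABP2, which encodes a retinoic acid binding protein, 796 CPM (781 to 810.2) in second heart field and pharyngeal-like cells. The fibronectin gene FN1 had 2037 CPM (2014 to 2059) in definitive endoderm-like cells. CCN2, a matricellular target of TGF-beta, had 367 CPM (353 to 382) in mesenchymal and smooth muscle-like cells. TOP2A, a topoisomerase gene of dividing cells, had 368 CPM (357 to 378) in cardiomyocyte-like cells.

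**Figure D4:**
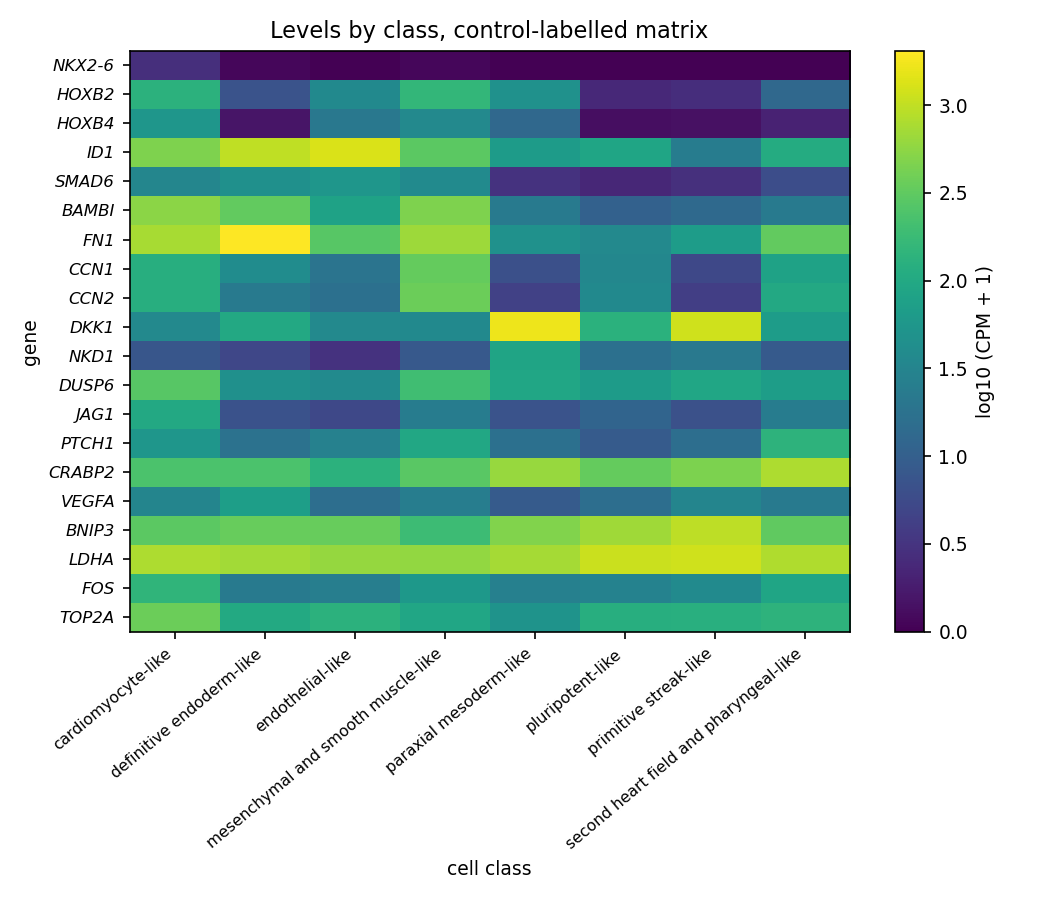
Levels of pathway genes and NKX2-6 in the named classes of the control-labelled matrix clustered alone, with genes as lines, classes as columns and colour giving log10 of CPM with 1 added. NKX2-6 reaches 1.76 CPM in cardiomyocyte-like cells, and DKK1 is highest in paraxial mesoderm-like cells at 1671 CPM. Class and hashtag population are confounded in these levels.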

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

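The tests of own-barcode correlation, of identical entries and of other barcode forms were chosen only after the result had been seen. In the knockdown-labelled hashtag library, 18892 of 29381 barcodes, 64.3%, carried exactly 1 of its 8 tags, a signal in data that no comparison of the report uses.

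That library shared 211 barcodes, 0.718%, with each expression matrix. Writing its barcodes in other forms did not recover the rest: the best form, with bases 8 and 9 complemented, matched 0.109%. The 211 shared barcodes do not behave as the same cells either, since 76.6% of the 94 with a control-labelled tag and 75.2% of the 117 without one carried a tag in it, a difference of 1.382 percentage points. That its cells may belong to an expression library other than these 2 stays open, and no biological explanation was tested.

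The 2 expression matrices share nearly every barcode. Separate libraries with barcodes shared by chance are argued against by the median own-barcode correlation of 0.986, above the highest value of 0.893 between different barcodes. The share of identical nonzero entries, 92.982%, is consistent with 1 library quantified 2 times. Which condition or conditions the cells came from stays open, as does the reason that the knockdown label is on the second matrix. The effect of the knockdown was not tested.

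Some genes, led by EEF1G and TOMM6, differ greatly between the matrices, and the joint clusters split by matrix. Of 115 genes at least 2-fold higher in the knockdown-labelled matrix, 99, or 86.087%, overlap a gene model listed only in the control-labelled reference, against 3.46% of genes within 1.1-fold, so reads shared with such models may account for these. For the 11 genes at least 2-fold lower, 4, or 36.364%, overlap a model listed only in the knockdown-labelled reference. Among genes within 1.1-fold 0.777% do. Only 1884 of these 3870 models had exons in GENCODE 29, against 724 of 806 models listed only in the control-labelled reference. Overlaps with the remaining models could not be seen, so the shares for the knockdown-labelled reference may be too low. For this reason, and with an interval of 10.9% to 69.2%, it stays open whether such overlaps account for most of the lower genes. MSGN1 among the higher genes overlaps none. With all genes, 38.9% of barcodes fell in the same cluster in both matrices. Without the 629 genes that differ by 0.5 log2 or more, 99.982% did, so the remaining genes did not split the clusters. The 629 genes were picked by their difference between these same matrices, and no other genes were removed for comparison. The outcome was therefore to be foreseen and is weak evidence that these genes caused the split. A biological cause is not among the explanations for this pattern, as the cells are the same.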

How the results depend on the processing

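Tests chosen only after the data had been seen were the hashtag thresholds at 0.5 and 2 times their value and the scaling of gene totals by the median gene ratio. Of 370 values under alternative settings, 241 stayed within the counting interval of the reported value and 129 left it. For ratios and medians of ratios that interval treats the matrices as independent, which they are not, so it is a yardstick only. NKX2-6 and AC012574.1, at 34 and at most 8 UMIs, stayed inside their intervals under each alternative tried, but depth limits both: without the added CPM, the log2 ratio of AC012574.1 ran from -0.05 to 0.19 and that of NKX2-6 from -0.09 to 0.02. No list median that could be computed left its interval with cells weighted equally or with a pseudocount of 0.1 CPM. The epicardial and septum transversum list gave no value with cells weighted equally, under the stricter filter or in hashtag singlets, nor the haematopoietic list in hashtag singlets. For the 26 other lists, 170 of 204 values stayed and 34 moved. Except where a scaling factor moved all genes alike, the cause was not tested. No paired comparison of conditions was possible, because each group had 1 sample and both expression matrices hold the same cells. Pairing by barcode was used only to compare the matrices with each other, not for the intervals of ratios.

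Under median-of-ratios scaling the pluripotent list had a median log2 ratio of -0.0011, the cardiac progenitor list 0.0018, the cardiomyocyte list 0.0126, the definitive endoderm list 0.0078 and the endothelial list -0.0050. The median over the other lists was 0.0035. This scaling shifts all genes alike, so the changed signs of medians this close to 0 follow from it and say nothing about the lists. In hashtag singlets the pluripotent list had -0.0627, the cardiomyocyte list -0.0225 and the definitive endoderm list -0.0244. The stricter filter, of at least 2000 UMIs and at most 10% mitochondrial UMIs, kept 12748 control-labelled and 13510 knockdown-labelled cells. The sets of cells therefore differed between the matrices, and the part of this in the moves was not tested. Under this filter the cardiomyocyte list had -0.0618 and the definitive endoderm list -0.0730. Under it the paraxial mesoderm list, at 0.0234, and the posterior HOX and CDX list, at 0.0347, had a changed sign. With every deposited barcode the cardiomyocyte list had -0.0436, and without a minimum CPM the endothelial list had -0.0158.

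Some class shares moved under each alternative. At Leiden resolution 0.5 no cluster was named primitive streak-like or mesenchymal and smooth muscle-like, and in hashtag singlets none was named paraxial mesoderm-like. These classes have no share there and are not among the 370 values, so their absence below does not mean that they stayed. MSGN1, a marker used to name paraxial mesoderm-like clusters, had 154 UMIs in the control-labelled and 24649 in the knockdown-labelled matrix. A control-labelled share of 0% for that class, below, therefore need not mean that such cells were absent. The reported clustering gave that share as 10.0%. Whether MSGN1 accounts for the 0% was not tested. At Leiden resolution 0.5 the control-labelled shares were cardiomyocyte-like 11.3%, paraxial mesoderm-like 0%, pluripotent-like 27.6% and second heart field and pharyngeal-like 2.15%. The knockdown-labelled shares were cardiomyocyte-like 11.4%, definitive endoderm-like 5.63%, pluripotent-like 27.4% and second heart field and pharyngeal-like 2.23%. At resolution 2 the control-labelled shares were cardiomyocyte-like 7.93%, mesenchymal and smooth muscle-like 1.62%, paraxial mesoderm-like 0%, pluripotent-like 23.0%, primitive streak-like 13.6% and second heart field and pharyngeal-like 7.41%. The knockdown-labelled ones were cardiomyocyte-like 7.93%, definitive endoderm-like 5.30%, mesenchymal and smooth muscle-like 1.62%, paraxial mesoderm-like 9.75%, pluripotent-like 24.2%, primitive streak-like 6.89% and second heart field and pharyngeal-like 7.41%. With each matrix clustered alone the control-labelled shares were cardiomyocyte-like 5.43% and primitive streak-like 11.4%. The knockdown-labelled ones were cardiomyocyte-like 5.53%, pluripotent-like 16.7% and primitive streak-like 15.8%. Under the stricter filter the control-labelled shares were cardiomyocyte-like 7.64%, definitive endoderm-like 6.65%, mesenchymal and smooth muscle-like 3.69%, paraxial mesoderm-like 0%, pluripotent-like 25.1%, primitive streak-like 5.08% and second heart field and pharyngeal-like 8.02%. The knockdown-labelled ones were cardiomyocyte-like 7.77%, definitive endoderm-like 6.33%, mesenchymal and smooth muscle-like 3.60%, paraxial mesoderm-like 14.7%, pluripotent-like 21.1%, primitive streak-like 7.32% and second heart field and pharyngeal-like 8.06%. With doublets kept the control-labelled shares were cardiomyocyte-like 4.80%, definitive endoderm-like 8.26%, endothelial-like 0.614%, mesenchymal and smooth muscle-like 4.28%, paraxial mesoderm-like 11.3%, pluripotent-like 22.5%, primitive streak-like 16.8% and second heart field and pharyngeal-like 7.20%. The knockdown-labelled ones were cardiomyocyte-like 4.81%, definitive endoderm-like 6.25%, endothelial-like 0.617%, mesenchymal and smooth muscle-like 4.30%, primitive streak-like 2.45% and second heart field and pharyngeal-like 7.22%. In hashtag singlets the control-labelled shares were cardiomyocyte-like 21.03%, definitive endoderm-like 11.5%, endothelial-like 1.00%, mesenchymal and smooth muscle-like 0%, pluripotent-like 7.12%, primitive streak-like 3.199% and second heart field and pharyngeal-like 18.1%. The knockdown-labelled ones were cardiomyocyte-like 18.2%, definitive endoderm-like 11.6%, endothelial-like 1.02%, mesenchymal and smooth muscle-like 3.01%, pluripotent-like 7.03%, primitive streak-like 3.00% and second heart field and pharyngeal-like 18.1%.

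Intervals of medians come from resampled counts, and those within mesenchymal and smooth muscle-like (-0.0366 to -0.0302) and second heart field and pharyngeal-like cells (-0.0410 to -0.0365) exclude the reported medians of -0.0378 and -0.0427, so the moves in these 2 classes say little. Within classes, the stricter filter gave median log2 ratios of -0.0396 for cardiomyocyte-like, -0.0394 for mesenchymal and smooth muscle-like, -0.0245 for pluripotent-like and -0.0456 for second heart field and pharyngeal-like cells. Without thinning, S phase was called for 24.95% and 26.4% of control-labelled and knockdown-labelled cells, and G2 or M phase for 18.95% and 18.7%. At 1000 UMIs per cell these were 15.1% and 13.4%, and 17.9% and 16.5%, so the order of the matrices turned for both phases. Doubled hashtag thresholds gave 40.02% of cells with exactly 1 tag. Scaling by the median gene ratio put 84.3% of genes within 1 Poisson SD, against 38.1% under total scaling.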

Other observations

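All values in this part were chosen only after they had been seen. Class and hashtag population are confounded in the levels by class here as well. In the control-labelled matrix clustered alone, single genes of the hypoxia and glycolysis list differed in where they were most abundant. BNIP3, a mitophagy receptor gene, had 947 CPM (938 to 956) in primitive streak-like and 679.9 CPM (675 to 685) in pluripotent-like cells, and the lactate dehydrogenase gene LDHA 1167 CPM (1157 to 1177) and 1099 CPM (1093 to 1105). VEGFA, an angiogenic growth factor gene, had 69.8 CPM (65.7 to 74.1) in definitive endoderm-like cells. HOXB2 had 153 CPM (144 to 163) in mesenchymal and smooth muscle-like and 135 CPM (129 to 141) in cardiomyocyte-like cells. SMAD6, an inhibitor of BMP signalling, had 54.4 CPM (40.6 to 71.3) in endothelial-like cells, and CCN1, a matricellular gene, 336 CPM (322 to 350.2) in mesenchymal and smooth muscle-like cells.

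The control-labelled hashtag library marks 5 populations, and the sources used here do not tie any of them to a condition. Of the 17282 control-labelled cells, C0251 marked 1361, C0252 981, C0253 1361, C0254 1328 and C0255 2159, while 755 carried several tags and 9337 none. With classes taken from the control-labelled matrix clustered alone, the largest named class differed between C0251, C0255 and the cells without a tag, and was second heart field and pharyngeal-like in C0252, C0253 and C0254. Of C0251 cells, 58.1% were definitive endoderm-like, 12.9% mesenchymal and smooth muscle-like and 4.92% endothelial-like. Of C0255 cells, 36.1% were cardiomyocyte-like and 12.3% second heart field and pharyngeal-like. Second heart field and pharyngeal-like cells made up 31.1% of C0252, 33.4% of C0253 and 20.5% of C0254 cells, and several unnamed clusters together held 56.8%, 57.5% and 68.6%. Cells without a tag were 44.7% pluripotent-like, 19.3% primitive streak-like and 16.7% paraxial mesoderm-like.

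NKX2-6 had 25 UMIs in C0255, 7 in C0251, 2 in cells with several tags and 0 in C0252, C0253, C0254 and cells without a tag. AC012574.1 had 6 UMIs in C0255, 1 in cells without a tag and 0 in the other populations. AC012574.2 had 8 UMIs in C0251, 4 in C0255, 1 each in C0253, C0254, cells with several tags and cells without one, and 0 in C0252. The BMP target ID1 had 684 CPM in C0251, 446 CPM in C0255, 80.8 CPM in C0252, 44.1 CPM in C0254 and 29.1 CPM in C0253. The pluripotency factor POU5F1 had 1066 CPM in cells without a tag and between 149 CPM (C0251) and 367 CPM (C0254) in the 5 tagged populations.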
